A study of Homo sapiens with 12 samples.

How the data were processed

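HBL-1 is an established cell line of the activated B-cell-like subtype of diffuse large B-cell lymphoma, a lymphoma in which NF-kB signalling is known to be chronically active. The cells were treated with MLN120B at 20 µM or with the carrier, DMSO, for 6, 12 or 24 h, and total RNA was profiled on 12 Illumina bead arrays of 1 chip, with 2 replicates in each of 6 groups. MLN120B is known as an inhibitor of IKKβ, a kinase that releases NF-kB from its IkB inhibitors. RNA was isolated on columns and amplified with biotin labelling, per the labels' protocols. Arrays were assigned to treatment, time and replicate from the sample labels. The labels do not say whether the replicates came from separate cultures, so p-values of single genes measure the spread between these arrays, which may be only technical.

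The deposited value table holds log2 expression values of 47309 probes on the 12 arrays. The software and the normalization that made it are not given in the sources used here. Set against the scanner data of the same arrays, its values ran in the same direction, were not centred by gene, lay below the raw log2 signal at the dim end and near it at the bright end, except in the DMSO array of 24 h, replicate 2, and had nearly the same medians and maxima on every array. Array medians lay between 5.14 and 5.17 and maxima between 15.91 and 16.01. The 0.7 quantile varied more, from 6.55 to 6.88. Values were missing in both arrays of a pair together, for 13 to 2844 probes. The deposited bead-level files hold the raw intensity of every bead with a bead-type code and a position, per the file headers, and carry no probe or gene name. Whether a local background had been taken off these intensities is not given in the sources used here.

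The value table was the main source, because no table given here ties bead codes to probes. This choice was fixed before the data were examined, as were the tests, the alternatives, the gene lists and the rule for naming genes. The platform annotation gave 1 gene symbol for 30108 probes, several for 8 and none for 17193. Probes of the last 2 kinds were left out of the gene tests. A gene table of assembly GRCh38.p14 was used for names alone, matched on the gene identifier: it changed 0 symbols, and 39 identifiers had no match. No coordinates are given, since the annotation used here names no build for the array.

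A probe was kept if its mean over the 12 arrays lay above the median of all probe means, 5.14. Each gene with a single symbol was then represented by its kept probe with the highest mean, which left 12302 of the 20043 genes with a probe. Of these 11500 had a value in all 6 pairs, and of the 802 others 734 lacked the 24 h pair of replicate 2. Where a gene had further kept probes, their values were computed as well.

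Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05 on the adjusted p. Genes lacking a pair were fitted on the pairs they had, and their variances were moderated together with the rest. The average effect of treatment was fitted with the pair, the arrays of the same time and replicate number, as a block of 6 levels, which left 5 residual degrees of freedom and 6.26 prior degrees of freedom. Effects at each time, and their differences between times, came from a fit of all 12 arrays with the same block. The change with time in carrier-treated cells came from 6 group means without a block. All differences are the arrays labelled MLN120B minus the arrays labelled DMSO, with standard errors from the fit. The series describes its measurements as pairs. Across 11500 genes, the deviations of same-numbered arrays from their group means correlated at 0.306 at 6 h, 0.268 at 12 h and 0.137 at 24 h, each above the limit of 0.1 set for taking the numbers as pairs. These correlations are across genes, which are not independent replicates. Same-numbered arrays of a time were also neighbours on the chip, so the correlations cannot tell a shared culture from adjacent position.

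Fixed gene lists, 33 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the lists. At this setting p comes from comparing the list's genes with the other genes, and does not measure the spread between arrays or pairs. The result of 1 list, which did not pass for the average effect, is left out of the text. Camera with a correlation estimated from the data and limma's fry were run as alternatives. The latter tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. Camera with an estimated correlation also has few degrees of freedom, the residual ones of the fit, 5 for the average effect. At the preset correlation they follow from the number of genes. A call lost between these tests need not come from correlation between genes. For JAK-STAT3 targets and components the estimate was -0.014, below the preset 0.01, yet camera's p went from 5.8e-08 to 0.0025. Members past the threshold were counted over all genes tested and adjusted over the list alone. A list of further NF-kB targets and a list of FOXO targets were added after the results had been seen and are used in the closing observations alone.

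Genes were named by rule: for the average effect the 12 largest falls and 12 largest rises past the threshold with the same sign in all 6 pairs; at each time the 5 largest falls and 5 largest rises past the threshold; for the change with time the 6 genes with the smallest F-test p; for each list the 4 members with the smallest p, whether or not they passed; and NFKBIZ, NFKBIA, NFKB1, NFKB2, REL, RELA, RELB, BCL3, IKBKB, CHUK, MYC, IL6, IL10, IRF4 and CD274 in any case. CD274 had no probe above the filter. Genes named outside this rule are said to be chosen after their values were seen.

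The alternatives were a fit without the pairs, the replicate number as a block, the chip position as a covariate without the pairs, quantile normalization, median centring, no filter, a filter that keeps the upper 30% of probes, the mean of a gene's probes, every probe on its own, a variance trend with robust moderation, array weights, a minimum change of 0.5 log2 units, an adjusted p under 0.01, and the removal of each pair in turn. The bead-level intensities were summarised per bead type after removal of beads over 3 median absolute deviations from the type's median, log2-transformed and quantile-normalized, without an offset, with an offset of 50 and, as a choice made after seeing the data, after normexp background correction with an offset of 16. They give counts of unnamed bead types. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

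The steps were tested on simulated data with the 12302 genes' own means and spreads, 50 genes changed at each size. For the average over times, 7 of the 50 genes changed by 0.5 log2 units, 42 of those changed by 1, 49 of those changed by 1.5 and 48 of those changed by 2 were recovered, with 11 unchanged genes called. For a change of 1 log2 unit at a single time 3 of 50 were recovered at 6 h, 4 at 12 h and 3 at 24 h, and for a change of 2 log2 units 31, 33 and 27. The F test of change with time recovered 22 of 50 genes at a difference of 2 log2 units and 40 at 3. The contrast of carrier-treated cells recovered 8 of 50 genes at 1 log2 unit and 40 at 2. The list test called 5 of 5 shifted lists and 0 of 20 unshifted lists. These were random lists whose genes varied independently, so the counts do not show how often lists of correlated genes are called falsely. In the data the estimated correlation was, for instance, 0.17 for hypoxia and glycolysis.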

Results

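Gene expression was measured in HBL-1 cells, a line of activated B-cell-like diffuse large B-cell lymphoma, after 6, 12 and 24 h with 20 µM MLN120B, an inhibitor of the NF-kB-activating kinase IKKβ, or with DMSO. Each of the 6 groups held 2 arrays, and each array labelled MLN120B was paired with the DMSO array of the same time and replicate number. The arrays held between 690218 and 1087463 beads, with 15 to 22 beads in the median bead type, and correlated with each other at 0.9694 to 0.9898 across genes, which are not independent replicates. Identical values were held by 0 pairs of arrays. All 12 arrays lay on 1 chip, with the 6 h arrays at positions A to D, the 12 h arrays at E to H and the 24 h arrays at I to L, so time and position cannot be told apart. Within each pair the array labelled MLN120B lay just before its DMSO array, in 6 of 6 pairs, so an effect of that order cannot be told apart from the arms either. Bead numbers fell along the chip, and the DMSO array of 24 h, replicate 2, had the fewest beads and an upper quartile of raw intensity of 437 units, against 255 to 320 on the other DMSO arrays. The small number of arrays limits the precision of every value below.

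**Figure D1:**
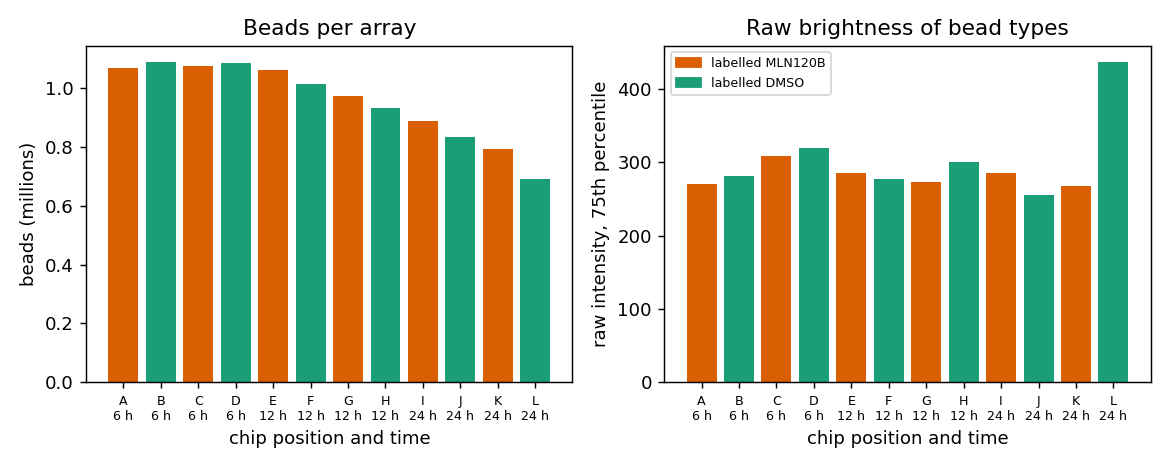
Beads on each array (left) and the upper quartile of the raw intensity of bead types (right), for the 12 arrays in chip order with their times; orange bars are arrays labelled MLN120B and green bars arrays labelled DMSO. Beads range from 690218 to 1087463, and the DMSO array at position L stands at 437 intensity units.

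The first comparison asked which transcripts differed between the arms in all pairs, averaged over the 3 times. NF-kB target genes, of which 9 of 33 measured rose, and interferon-induced genes, of which 4 of 26 rose, were higher in the arrays labelled MLN120B. For NF-kB targets this direction is opposite to that known for an IKKβ inhibitor. No transcript in this design checks the labels independently, so arms are named by their labels throughout, and every direction rests on them. LRRC32, the cell-surface carrier of latent TGF-beta, was 4.43-fold higher, at 9.24 ± 0.52 against 7.09 ± 0.30 log2 units (SD, n = 6 arrays each). FST, the secreted activin antagonist follistatin, was lower, at 6.80 ± 0.51 against 8.57 ± 0.29 log2 units and thus 3.40-fold higher in the DMSO arrays. Of 12302 genes tested, 60 fell and 43 rose, and 102 of these 103 had the same sign in all pairs measured. Of the 103, 30 differed by at least 1 log2 unit.

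Among the 12 named rises, LRRC32 rose by 2.15 ± 0.22 log2 units (SE, adjusted p = 0.00207), higher in 6 of 6 pairs, as the naming rule required of every named rise. IFI44L, IFIT1 and IFIT3, members of the interferon-induced programme, rose by 1.91 ± 0.19, 1.61 ± 0.21 and 1.26 ± 0.19 (adjusted p = 0.00207, 0.00839 and 0.0191). CCL22, a chemokine that attracts CCR4-bearing T cells, rose by 1.74 ± 0.17 (adjusted p = 0.00207), and the cytokine TNF by 1.20 ± 0.14 (adjusted p = 0.00523). SOCS3, a feedback inhibitor of JAK-STAT signalling, rose by 1.25 ± 0.20 (adjusted p = 0.0233). RASSF4, a Ras-association domain protein, and MYO7A, an unconventional myosin, rose by 1.38 ± 0.17 and 1.34 ± 0.15 (adjusted p = 0.00767 and 0.00476). DEPP1, a known FOXO target, ADGRE1, an adhesion G-protein-coupled receptor, and ABTB2 rose by 1.29 ± 0.21, 1.19 ± 0.24 and 1.14 ± 0.19 (adjusted p = 0.0244, 0.0448 and 0.0244).

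Among the 12 named falls, each lower in 6 of 6 pairs by the naming rule, FST fell by 1.77 ± 0.15 log2 units (SE, adjusted p = 0.00148). The histone genes H2BC5 and H4C8 fell by 1.19 ± 0.14 and 1.11 ± 0.22 (adjusted p = 0.00476 and 0.0441). KLHL24, a kelch-like substrate adaptor of CUL3 ubiquitin ligases, and CCNG2, an atypical cyclin linked to cell-cycle exit, fell by 1.19 ± 0.17 and 1.15 ± 0.15 (adjusted p = 0.0147 and 0.00963). HLA-DOB, a subunit of the HLA-DO regulator of class II peptide loading, fell by 1.08 ± 0.17 (adjusted p = 0.0226). NSG1, an endosomal sorting protein, ARSG, a lysosomal sulfatase, and AGPAT4, an acyltransferase of phospholipid synthesis, fell by 1.15 ± 0.14, 1.06 ± 0.17 and 0.99 ± 0.16 (adjusted p = 0.00706, 0.0229 and 0.0244). FMO4, a flavin-containing monooxygenase, HSF5, a heat shock factor family member, and CCDC92 fell by 1.24 ± 0.25, 0.98 ± 0.18 and 1.00 ± 0.17 (adjusted p = 0.0479, 0.0374 and 0.0301). The CCDC92 difference of the 24 h pair of replicate 2, -1.96, lay far from the other 5.

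**Figure D2:**
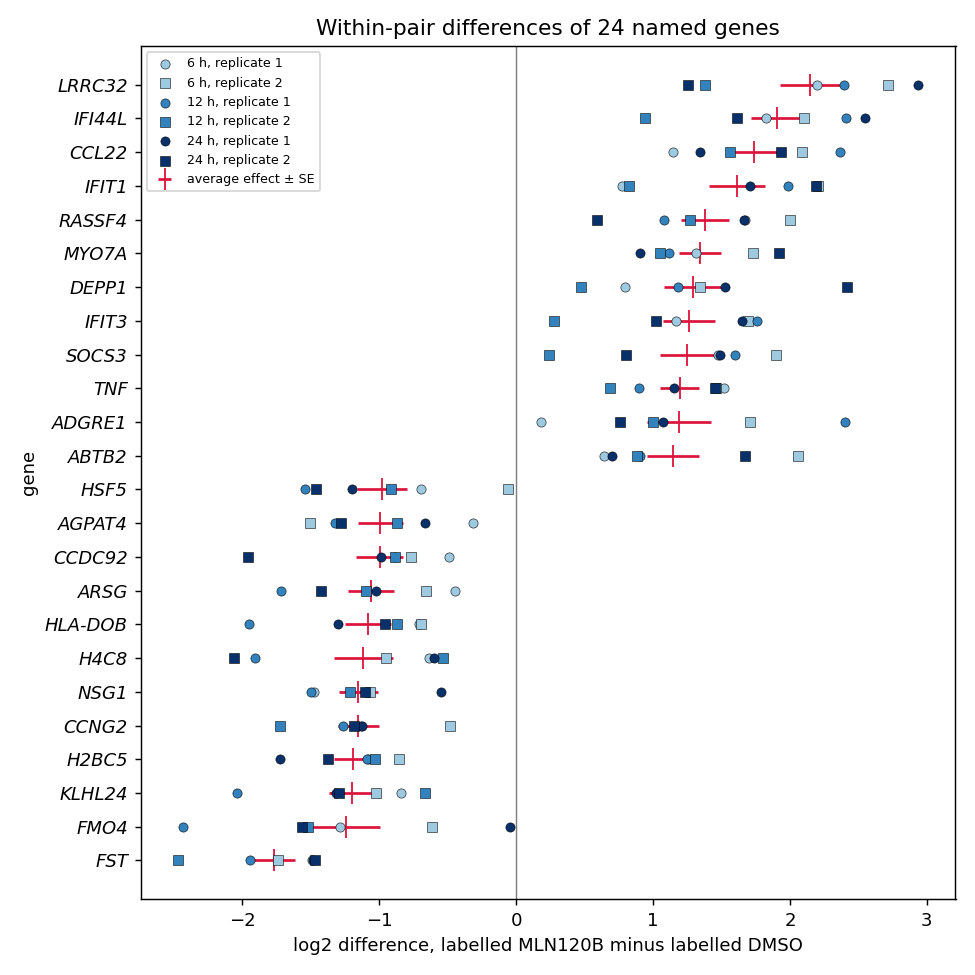
Log2 difference, labelled MLN120B minus labelled DMSO, of the 24 genes named for the average effect; points are the 6 pairs, shaded by time and shaped by replicate, and red bars the fitted average ± SE. By the naming rule all points of the 12 rises lie above 0 and all points of the 12 falls below 0. The averages run from -1.77 for FST to 2.15 for LRRC32.

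Further probes of the genes named for the average effect gave smaller differences: -0.43 for FST, -0.51 and -0.15 for CCNG2, -0.47 for H2BC5, 0.42 for IFI44L, 0.71 and 0.32 for IFIT3, 0.21 for SOCS3 and 0.60 for RASSF4. FST, LRRC32, IFI44L, IFIT1, MYO7A and TNF were past the threshold in all 18 alternative settings in which named genes could be tested, and HSF5 and FMO4 in 6 of 17. The counts moved with the fit: without the pairs as a block 10 genes were lower and 16 higher, with the replicate number as a block 9 and 15, with chip position as a covariate and no block 4 and 7, and with a variance trend and robust moderation 176 and 130. Leaving out the 6 h pairs of replicates 1 and 2, the 12 h pairs of replicates 1 and 2, and the 24 h pairs of replicates 1 and 2 in turn gave 22, 13, 7, 19, 9 and 10 lower genes and 22, 10, 11, 25, 10 and 25 higher genes.

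The series concerns NF-kB signalling and the atypical IkB protein NFKBIZ. NF-kB target genes of activated B cells lay higher as a group in the arrays labelled MLN120B: 9 of 33 measured members rose and 0 fell, and 20 rose when adjusted over the list alone. The median difference was 0.48 log2 units, positive in 6 of 6 pairs (camera, adjusted p = 1.2e-30; adjusted p = 0.0356 with an estimated correlation). CCL22 and TNF were 2 of the 9. CD40, the costimulatory receptor of B cells, rose by 1.01 ± 0.12 (adjusted p = 0.00516) and EBI3, a subunit of IL-27 and IL-35, by 1.14 ± 0.15 (adjusted p = 0.0107). The list of NF-kB subunits and IkB proteins, which shares members with the target list, rose too. Of its 11 members 2 passed the threshold, 6 when adjusted over the list alone, and the median was 0.38 (adjusted p = 3.07e-07; adjusted p = 0.0356 with an estimated correlation).

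Of these, NFKBIA, the IkB-alpha inhibitor and itself an NF-kB target, rose by 0.86 ± 0.14 (adjusted p = 0.0247), higher in 6 of 6 pairs. NFKB2, the p100/p52 subunit, rose by 0.72 ± 0.15 (adjusted p = 0.0498), higher in 6 of 6. Across the 18 alternative settings NFKBIA kept its call in 11 and NFKB2 in 7, against 17 for CD40 and 16 for EBI3. NFKBIZ did not pass: its difference was 0.49 ± 0.16 (adjusted p = 0.182), positive in 5 of 6 pairs, at 12.67 ± 0.30 against 12.17 ± 0.41 log2 units (SD, n = 6). NFKB1 and BCL3 differed by 0.47 ± 0.11 and 0.56 ± 0.14 (adjusted p = 0.0902 and 0.0956), and RELB and RELA by 0.38 ± 0.12 and 0.38 ± 0.17 (adjusted p = 0.158 and 0.329). REL stood at -0.27 ± 0.12 (adjusted p = 0.311). The IKK genes IKBKB and CHUK stood at 0.19 ± 0.13 and -0.002 ± 0.15 (adjusted p = 0.551 and 0.996), with -0.45 at a further IKBKB probe. MYC, IRF4, IL6 and IL10 stood at 0.25, 0.43, 0.085 and -0.065 (adjusted p = 0.409, 0.182, 0.897 and 0.895).

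The feedback inhibitors of NF-kB had 1 riser of 10 members, NFKBIA, with 2 when adjusted over the list alone and a median of 0.20 (camera, adjusted p = 0.00519; adjusted p = 0.139 with an estimated correlation). USP18, also an interferon-induced gene, TNIP1 and N4BP1 differed by 0.87, 0.32 and -0.25 and did not pass. Anti-apoptotic genes had 1 riser of 14, BCL2L1, which encodes BCL-XL and rose by 0.82 ± 0.15 (adjusted p = 0.0345). BCL2L1 kept its call in 8 of 18 alternative settings. IER3, GADD45B and CFLAR, which are also on the NF-kB target list, differed by 0.59, 0.58 and 0.30. For this list 3 members passed when adjusted over the list alone and the median was 0.21 (adjusted p = 0.00377; adjusted p = 0.124 with an estimated correlation). In the pro-apoptotic BCL2 family 0 of 11 members passed by either count (adjusted p = 0.978), with BIK at -0.38, BID at 0.30, BMF at 0.22 and BCL2L14 at -0.27.

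Interferon-induced genes rose as a group in the arrays labelled MLN120B. Of 26 members 4 rose, 9 when adjusted over the list alone, and the median was 0.32, positive in 6 of 6 pairs (camera, adjusted p = 1.65e-13; adjusted p = 0.0472 with an estimated correlation). The 4 were IFI44L, IFIT1, IFIT3 and MX1, an interferon-induced antiviral GTPase that rose by 0.93 ± 0.16 (adjusted p = 0.0296). MX1 kept its call in 9 of 18 alternative settings. JAK-STAT3 targets and components rose with 2 of 19 members, 8 when adjusted over the list alone, and a median of 0.22 (adjusted p = 4.8e-07; adjusted p = 0.0356 with an estimated correlation). BATF, a transcription factor of the AP-1 family, rose by 1.01 ± 0.14 (adjusted p = 0.0132) beside SOCS3, while JUNB and BCL3 differed by 0.55 and 0.56. BATF and JUNB are also on the NF-kB target list, and BCL3 on the list of subunits and IkB proteins, so this call is not separate from theirs. Cytokines and chemokines had 3 risers of 14, CCL22, TNF and EBI3, and IL12A at 0.66 ± 0.14 (adjusted p = 0.0773, higher in 5 of 5 pairs). All 3 risers are also on the NF-kB target list. Adjusted over the list alone, 4 were higher and 1 lower; the median was 0.17 (adjusted p = 8.59e-07; adjusted p = 0.118 with an estimated correlation).

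Genes of class II antigen presentation lay lower in the arrays labelled MLN120B, and all 9 measured members had negative differences. Of these 1 fell, 2 when adjusted over the list alone, and the median was -0.31, negative in 6 of 6 pairs (camera, adjusted p = 1.05e-04; adjusted p = 0.139 with an estimated correlation). HLA-DOB was the member that fell. HLA-DOA, its partner chain, differed by -0.76 ± 0.17 (adjusted p = 0.0803), and HLA-DMB and CIITA, the class II transactivator, by -0.31 and -0.35. The germinal centre programme had 0 of 10 members past limma's threshold, 1 when adjusted over the list alone, and a median of -0.23 (adjusted p = 0.0283; adjusted p = 0.139 with an estimated correlation). Its call ended with array weights (adjusted p = 0.0603), and without the 12 h pair of replicate 2, the 24 h pair of replicate 1 or the 24 h pair of replicate 2 (adjusted p = 0.116, 0.0667 and 0.0672 for the list germinal centre programme). ID3, an inhibitor of E-protein transcription factors, RGS13, MME and ELL3 differed by -0.48, -0.32, -0.32 and -0.24.

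B cell surface molecules had 2 risers of 19, CD40 and ICAM1, an adhesion molecule that rose by 1.36 ± 0.21 (adjusted p = 0.024) and was higher in 5 of the 5 pairs with a value. Both risers are also on the NF-kB target list. Adjusted over the list alone, 4 were higher and 1 lower, and the median was 0.14 (camera, adjusted p = 6.74e-04; adjusted p = 0.139 with an estimated correlation). CD69 and CD80, markers of lymphocyte activation, differed by -1.08 ± 0.24 and 0.71 ± 0.17 (adjusted p = 0.0785 and 0.0825). In the B cell identity list 1 of 19 members fell, also 1 when adjusted over the list alone: VPREB3, a protein tied to the pre-B-cell receptor, fell by 0.83 ± 0.15 (adjusted p = 0.0345). MS4A1, which encodes CD20, FCRLA and CR2 differed by -0.42, -0.34 and 0.36, and the list did not pass camera (median -0.13, adjusted p = 0.17). It did pass fry (adjusted p = 0.0309) and, with the upper 30% filter, camera (adjusted p = 0.0466 for the list B cell identity). The plasma cell programme had 0 of 15 members past the threshold and 2 lower ones when adjusted over the list alone (median -0.039, adjusted p = 0.779), with TNFRSF17 at -0.72, JCHAIN at -0.84, IRF4 at 0.43 and ELL2 at 0.66. Class I antigen presentation had 0 of 13 by either count (median 0.071, adjusted p = 0.404), with TAP2 at 0.63, HLA-E at -0.21, TAPBP at 0.24 and ERAP1 at -0.23; a further TAP2 probe stood at -0.007.

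**Figure D3:**
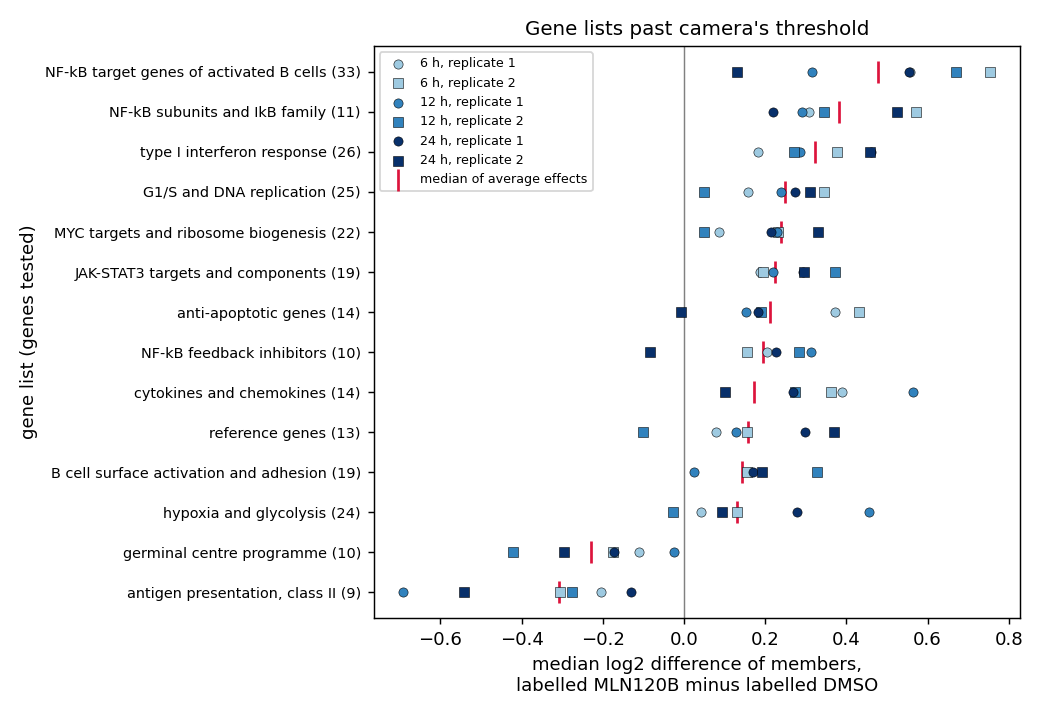
Median log2 difference, labelled MLN120B minus labelled DMSO, of the members of the 14 gene lists past camera's threshold at the preset correlation, with the number of genes tested in brackets; points are the 6 pairs, and red bars the median of the members' average effects. The medians run from -0.31 for class II antigen presentation to 0.48 for NF-kB target genes. With an estimated correlation, and the fewer degrees of freedom of that test, 4 of the 14 calls hold.

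Growth-related lists lay slightly higher in the arrays labelled MLN120B, with 0 single members past limma's threshold. For G1/S and DNA replication the median of 25 genes was 0.25, positive in 6 of 6 pairs (camera, adjusted p = 9.74e-07; adjusted p = 0.118 with an estimated correlation). GINS1, CHAF1A, CCNE1 (cyclin E1) and MCM4, a subunit of the replicative helicase, differed by 0.47, 0.49, 0.39 and 0.39. For MYC targets and ribosome biogenesis the median of 22 genes was 0.24, positive in 6 of 6 pairs (adjusted p = 7.66e-05; adjusted p = 0.139 with an estimated correlation). SRM (spermidine synthase), MRTO4, NOB1 and RRP9 differed by 0.50, 0.46, 0.44 and 0.47. Adjusted over the list alone, 0 members of either list passed. The hypoxia and glycolysis list had a median of 0.13 over 24 genes, with 0 past the threshold and 1 when adjusted over the list alone (adjusted p = 0.00965; adjusted p = 0.377 with an estimated correlation). Its call ended with fry (adjusted p = 0.223) and without the 12 h pair of replicate 1 (adjusted p = 0.147 for the list hypoxia and glycolysis). ALDOA, a glycolytic enzyme, ADM, PFKFB4 and ANKRD37 differed by 0.59, -0.59, 0.48 and 0.30, with -0.006 at a further ALDOA probe.

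Reference genes, used as stable standards in many assays, also lay higher, with a median of 0.16 over 13 genes, 0 past limma's threshold and 0 when adjusted over the list alone (camera, adjusted p = 0.019; adjusted p = 0.315 with an estimated correlation). TUBA1B, TFRC, EEF1A1 and SDHA differed by 0.48, 0.28, 0.24 and 0.25. For the list reference genes the call ended after quantile normalization (adjusted p = 0.0553), with fry (adjusted p = 0.144) and without either 24 h pair (adjusted p = 0.0926 and 0.0957). The median difference over all 12302 genes was -0.015.

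Stress and metabolic lists had 0 members past limma's threshold over all genes, and camera at the preset correlation called 0 of these 7 lists. For p53 targets fry gave a call (adjusted p = 0.00978), as did camera without the filter (adjusted p = 0.0425 for the list p53 targets). The list heat shock response passed camera with the mean of a gene's probes, with a variance trend and robust moderation, and without either 6 h pair (adjusted p between 0.0214 and 0.0382). The medians of the 7 lists were -0.13 over 18 p53 targets (adjusted p = 0.139), -0.013 over 17 genes of the unfolded protein and integrated stress response (adjusted p = 0.978), and 0.14 over 11 heat shock genes (adjusted p = 0.0615). They were -0.11 over 9 oxidative stress genes (adjusted p = 0.80), -0.11 over 4 aryl hydrocarbon receptor genes (adjusted p = 0.762), -0.007 over 15 cholesterol synthesis genes (adjusted p = 0.535) and 0.009 over 22 oxidative phosphorylation genes (adjusted p = 0.578). TP53INP1, the single member of the p53 list that passed when adjusted over the list alone, differed by -0.74 ± 0.17, and TP53I3, SESN1 and CCNG1 by -0.49, -0.40 and -0.19. In the other 6 lists the count adjusted over the list alone was 0. PHGDH, DDIT3, DNAJB9 and EDEM1 of the stress response differed by 0.27, -0.37, -0.20 and -0.18, and the chaperone genes CHORDC1, HSPA4L, HSPA1B and HSPA8 by 0.27, 0.23, 0.30 and 0.19. GCLC and GCLM, the subunits of the enzyme that starts glutathione synthesis, differed by -0.43 and 0.41, SRXN1 and TXN by 0.37 and 0.27, and TIPARP, NQO1, NFE2L2 and ALDH3A1 by -0.15, -0.11, -0.11 and 0.20. NSDHL, LSS, SC5D and DHCR7 of cholesterol synthesis differed by 0.36, 0.23, -0.21 and 0.17, and SDHA, UQCRC2, ATP5F1A and COX6C of the respiratory chain by 0.25, -0.26, 0.21 and 0.21.

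Mitotic genes had 0 of 25 members past the threshold by either count (adjusted p = 0.578), with AURKB at 0.50, CCNA2 at 0.27, CCNB1 at -0.25 and MKI67 at 0.30. Cytosolic ribosomal proteins had 0 of 30 by either count and a median of 0.018 (adjusted p = 0.675), with RPL28 at -0.48, RPS2 at 0.41, RPL37 at -0.33 and RPL13 at -0.40; a further RPL13 probe stood at 0.36. Immediate early genes had 0 of 20 past the threshold, 4 higher when adjusted over the list alone, and a median of 0.070 (camera, adjusted p = 0.0615), with JUNB, IER3, IER5 and DUSP2 at 0.55, 0.59, 0.44 and 0.54. The list immediate early genes passed camera with the upper 30% filter, the mean of a gene's probes, and without the 24 h pair of replicate 2 (adjusted p = 0.00982, 0.0388 and 0.0335). Markers of other cell types gave no list call by camera or fry: 0 of 5 T and NK cell genes passed (adjusted p = 0.845), 0 of 7 monocyte and granulocyte genes (adjusted p = 0.978), 0 of 4 fibroblast, endothelial and epithelial genes (adjusted p = 0.294) and 0 of 3 erythroid and megakaryocyte genes (adjusted p = 0.978). Adjusted over the list alone 1 of these was lower, PECAM1 at -0.52. EPCAM, KRT19 and KRT18 stood at -0.14, -0.23 and 0.059. PRF1, GZMB, CD8A and CD2 stood at -0.24, 0.076, -0.084 and -0.078, and the myeloid markers FCGR3A, ITGAM, CSF1R and S100A8 at -0.33, -0.20, 0.23 and 0.14. HBA2, ALAS2 and PPBP stood at -0.11, 0.029 and -0.020.

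Further probes of list members and NF-kB genes did not always match the values above. Besides those already given, the sign was opposite for GCLM at -0.15, IL10 at 0.34, N4BP1 at 0.16, DHCR7 at -0.011, and for single probes of TAPBP at -0.14 and EEF1A1 at -0.13. Under 0.5 times the size were CD69 at -0.39, NFKBIZ at 0.18, CCNE1 at 0.058, HSPA8 at 0.051, ATP5F1A at 0.10, FCGR3A at -0.036 and a probe of EEF1A1 at 0.052. Over 1.5 times the size were BID at 0.52 and 0.88 (adjusted p = 0.14 and 0.286 over all probes), LSS at 0.49, TAPBP at 0.37 and EPCAM at -0.32.

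The fixed list of NF-kB target genes lay higher in the arrays labelled MLN120B at each time. At 6 h the median of the NF-kB target list was 0.64 (camera, adjusted p = 1.26e-31), at 12 h 0.46 (adjusted p = 5.51e-13) and at 24 h 0.39 (adjusted p = 6.02e-09). The interferon list stood at 0.27, 0.26 and 0.41 (adjusted p = 3.78e-11, 1.23e-04 and 3.65e-08), and class II antigen presentation at -0.25, -0.34 and -0.36 (adjusted p = 0.129, 0.0039 and 0.00357). In all, 10 of 33 lists passed at 6 h, 9 at 12 h and 9 at 24 h. Without the 12 h pair of replicate 1 it was 1 list at 12 h, and without the 24 h pair of replicate 2 it was 3 lists at 24 h. For the treatment effect, an estimated correlation was run for the average alone. The camera p-values at single times set list genes against other genes, and do not measure the spread between the pairs of a time.

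Each single time rests on 2 pairs. At 12 h FST fell by 2.21 ± 0.23 log2 units (SE, adjusted p = 0.0479), lower in both pairs, and 0 genes rose. FST stood at -1.62 at 6 h and -1.48 at 24 h. limma called 0 genes at 6 h, where 623 had an unadjusted p under 0.05 against 615 expected by chance, and 0 at 24 h, where 1242 did. At 12 h 1135 did. A variance trend with robust moderation called 1 lower and 7 higher genes at 6 h, 4 and 13 at 12 h, and 8 and 13 at 24 h. Among the unnamed bead types these counts were 1 and 10, 6 and 25, and 9 and 13 without an offset, 1 and 5, 1 and 1, and 5 and 7 with an offset of 50, and 1 and 7, 1 and 1, and 1 and 4 after normexp correction. Without the 12 h pair of replicate 1, 2 genes fell and 15 rose at 12 h, and without that of replicate 2 0 fell and 1 rose. FST at 12 h lost its call without the pairs as a block (adjusted p = 0.0989), with the mean of its probes (adjusted p = 0.287), with array weights (adjusted p = 0.0594), and without any single pair other than the 12 h pair of replicate 1 (adjusted p between 0.128 and 0.235).

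The difference between times was tested itself. For the F test over the 3 times limma called 0 of 12302 genes, with 520 at an unadjusted p under 0.05 against 615 expected by chance, and 0 genes for 12 h against 6 h (507 unadjusted) and for 24 h against 6 h (520 unadjusted). SNORA70C, a small nucleolar RNA gene, had the smallest F-test p (adjusted p = 0.853), with differences of -1.12, 1.32 and 0.19 at 6, 12 and 24 h. CEP170, UNC5CL, GIGYF1, ZNF276 and ZBTB18 followed (adjusted p = 0.999 each). Of the 33 lists 0 changed between times; for NF-kB target genes the adjusted p was 0.546 for 12 h against 6 h and 0.302 for 24 h against 6 h. Every probe tested on its own, and the bead types, gave 1 call each for the F test and for 24 h against 6 h, and with a normexp correction the bead types gave 0. Without the 12 h pair of replicate 1, 1 gene passed the F test and 1 the test of 12 h against 6 h.

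Gene-wise differences at separate times, which share no arrays, correlated across genes at 0.262 (6 and 12 h), 0.269 (6 and 24 h) and 0.304 (12 and 24 h); genes are not independent replicates. Of the 115 genes with an unadjusted p under 0.01 at 6 h, 76.5% had the same sign at 12 h and 80.9% at 24 h. Of the 290 such genes at 12 h, 74.1% had the same sign at 6 h and 78.6% at 24 h, and of the 323 at 24 h, 79.3% at 6 h and 82.7% at 12 h. Over all genes these shares lay between 58.1% and 58.8%.

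The last comparison asked how carrier-treated cells changed in culture, with the DMSO arrays of 24 h set against those of 6 h; time and chip position cannot be told apart here. limma called 0 of 12302 genes. At an unadjusted p under 0.05, 456 were lower and 467 higher at 24 h, 923 in all against 615 expected by chance, and the smallest adjusted p was 0.141. FST stood at -0.49 ± 0.32, H2BC5 at 0.86 ± 0.39 and KLHL24 at 0.46 ± 0.55 (SE), with adjusted p = 0.762, 0.663 and 0.886. A variance trend with robust moderation called 4 lower genes and 0 higher ones, and the bead types 1 lower and 0 higher without an offset or with an offset of 50, and 0 after normexp correction.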

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

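In this part, the tests of a rise with correct labels and of the order of arrays within pairs, the comparison of residual spreads and the normexp background correction were chosen after the results they bear on had been seen, and the list of further NF-kB targets was drawn up after the pattern it tests. The 6 arrays or pairs of a group span 3 times, so a value can stand apart through time or chip position as well as through a single array. Of 66 groups of 6 values examined, 8 had an end value whose gap to the rest, as a share of the range, passed Dixon's critical value. Chance would give 3.3 if the groups were separate tests. Many of them measure the same arrays, so no excess over chance can be read from these numbers.

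Most of these gaps concern the 24 h arrays of replicate 2, at the end of the chip. The DMSO array had 46174 bead types, against 48112 to 48323 on the other DMSO arrays, and its upper quartile of raw intensity was 437, against 255 to 320. The MLN120B array of that pair had 47637 bead types, against 48271 to 48323. The value table lacked 2844 probes in this pair, in the DMSO array and equally 2844 in the MLN120B array, against 13 to 267 in the other pairs. The upper quartile of the table's values was 7.66 in the DMSO array of 24 h, replicate 1, against 7.74 to 7.76, and the maximum was 15.91 in the DMSO array of 12 h, replicate 2, against 15.96 to 15.98. For CCDC92 the difference of the 24 h pair of replicate 2 was -1.96, against -0.99 to -0.49 in the other pairs. Principal components were not among the groups examined. On the second of them the DMSO array of 12 h, replicate 2, stood at -41.45, against -9.15 to 4.47 on the other DMSO arrays. Its pair had the lowest array weight, 0.662. Outside the gene tests, limma put 2 of 6933 probes without a single gene symbol past the threshold, both higher in the arrays labelled MLN120B, and 0 were lower.

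NF-kB target genes of the fixed list, the first list below, were higher in the arrays labelled MLN120B, although IKKβ inhibition is known to lower such genes. With position as a covariate, the mean difference of the 29 list members with complete values was 0.55 ± 0.058 (SE), against 0.51 without it. Within a time, position is fixed by replicate number and arm, so that fit takes its slope from the difference between replicates. It cannot decide whether a gradient of position along the chip is the cause. Columns exchanged between the value table and the bead-level files are argued against as the cause. Among 1500 bright probes the nearest bead types lay closer with the columns as deposited in 6 of 6 pairs. Labels of the arms exchanged in every pair may account for the direction, and so may a rise of these genes under MLN120B with correct labels or an effect of the order within pairs, since the array labelled MLN120B comes first in 6 of 6; these cannot be told apart, because each goes with the rise of the first list seen in 6 of 6 pairs. A list of further NF-kB targets had a positive median in 4 of 6 pairs. That is short of the 5 that exchanged labels were taken to need and above the 3 taken to exclude them. At 6, 12 and 24 h the median of this further list was 0.13, 0.18 and 0.024 (camera, adjusted p = 0.0169, 0.014 and 0.423 over the 2 added lists). Over its 41 genes the median was 0.056 (camera, adjusted p = 0.00848 over the 2 added lists; adjusted p = 0.0755 with an estimated correlation), and over the 35 genes that no other list holds 0.021 (adjusted p = 0.124).

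Far fewer probes passed in the value table than bead types in the bead-level intensities, 34 against 561, for the average effect. A normexp background correction with an offset of 16 lowered that number to 198, and an offset of 50 without the correction left 305 lower and 255 higher. The handling of background may therefore be a part of the difference. The remaining gap to 34 argues against these settings as the whole cause, and no other handling of background was tried. Among the brightest 20% of probes, where background matters least, the median residual SD was 27.8% higher in the value table, at 0.199 against 0.156. The bead-level values of that comparison had no background correction, so the excess does not isolate what remains after it. A less precise summary of beads in the value table is a candidate explanation that was not separated from background handling. No biological explanation was tested, since both sources describe the same arrays.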

How the results depend on the processing

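All alternatives were planned before the data were examined except the normexp correction, and 0 results reversed; the cause of a changed count was not tested unless stated. Over all settings, 2413 of 2641 values of named genes kept their side of the threshold, 188 lost their call and 40 gained one; for lists it was 495, 20 and 11 of 526. Of the 2413 gene values 26 changed sign, as did 26 of the 495 list values, with neither value past the threshold. Median centring, no filter and a minimum change of 0.5 moved no count of genes past the threshold by over 1.5 times. Without a replicate block, 10 genes were lower and 16 higher for the average effect, all 26 shared with the 103 called, 0 lower at 12 h, and no list call of the average effect changed. With the replicate number as a block it was 9 and 15, and with chip position as a covariate in place of the replicate block 4 and 7. Within a time, position is fixed by replicate number and arm, so these settings are not separate checks. The upper 30% filter, which tests fewer genes, gave 112 and 74 for the average effect, 1 and 3 at 6 h, and 2 lower at 12 h. The mean of a gene's probes gave 0 lower at 12 h. Every probe on its own gave 15 and 19 for the average effect, 0 lower at 12 h, 1 lower at 24 h, 1 for the F test and 1 for 24 h against 6 h. Trend and robust eBayes gave 176 and 130, with 94 of the 103 shared, 1 and 7 at 6 h, 4 and 13 at 12 h, 8 and 13 at 24 h, and 4 lower in carrier-treated cells. Array weights gave 135 genes, with 101 of the 103 shared, 2 and 5 at 6 h, 0 at 12 h, and 1 lower list. Quantile normalization gave 46 and 46, with 88 of the 103 shared. Adjusted p under 0.01, a stricter threshold by construction, gave 4 and 8 for the average effect and 0 at 12 h. Bead-level values gave 306 and 255 bead types for the average effect, 1 and 10 at 6 h, 6 and 25 at 12 h, 9 and 13 at 24 h, 1 for the F test, 1 for 24 h against 6 h, and 1 lower in carrier-treated cells. With offset 50 these were 305 and 255, 1 and 5, 1 and 1, 5 and 7, 1, 1 and 1. With normexp and offset 16 they were 107 and 91, 1 and 7, 1 and 1, and 1 and 4. Camera with an estimated correlation kept 0 lower and 4 higher lists, and fry called 4 lower and 10 higher.

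Leaving out each pair in turn, which removes samples and residual degrees of freedom, gave 7 to 22 lower and 10 to 25 higher genes for the average effect (22, 13, 7, 19, 9 and 10 lower and 22, 10, 11, 25, 10 and 25 higher without the 6 h, 12 h and 24 h pairs of replicates 1 and 2 in this order), 0 to 2 lower and 0 to 15 higher at 12 h, 0 to 1 genes for the F test, 0 to 1 for 12 h against 6 h, and 1 to 2 lower and 11 to 13 higher lists. Where a time was left with a single pair, that pair was assumed to vary like the others. The 15 higher genes at 12 h and the calls for the F test and for 12 h against 6 h came without the 12 h pair of replicate 1, and the single lower list without the 12 h pair of replicate 2 or either 24 h pair. A constant of 16 before log2 was not run, since the table is not linear, and the bead-level files gave no value for named genes or lists. Signal over background is low for genes near the filter of 5.14: at the median of an array the deposited value lay 1.78 to 1.96 log2 units below the raw one, so differences there rest on how background was removed.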

Other observations

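The tests of carrier-treated lists and the genes and gene families of the next paragraph were chosen after the values had been seen; the tests of splits and of FOXO targets were set out before their results were known, the latter on a pattern already noticed.

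Beyond the genes named by rule, 3 further histone genes were lower in the arrays labelled MLN120B: H2AC11 stood at -0.95 ± 0.18 log2 units (adjusted p = 0.0432, lower in 6 of 6 pairs), H2AC6 at -0.93 ± 0.18 (adjusted p = 0.0448, lower in 5 of 6) and H2BC11 at -0.89 ± 0.18 (adjusted p = 0.0484, lower in 6 of 6). Of 52 histone genes tested, 5 were lower and 0 higher by limma, and 39 had negative differences (median -0.19). Small non-polyadenylated RNAs of splicing and ribosome maturation, RNU4-1, RNU4-2 and SNORD3A, stood at -0.88, -0.69 and -0.64 (adjusted p = 0.0345, 0.0448 and 0.0448). They were the 3 of 172 small nuclear and nucleolar RNA genes that passed, and 103 of the 172 had positive differences (median 0.067). Neither family was tested as a list. TNFSF10, which encodes the death ligand TRAIL, stood at -0.91 (adjusted p = 0.0226), MXD1, an antagonist of MYC at shared DNA sites, at -0.98 (adjusted p = 0.0244), the cholesterol exporter ABCG1 at -0.82 (adjusted p = 0.0151), the chemokine CXCL16 at -0.87 (adjusted p = 0.0197) and the transcription factor MEF2C at -0.67 (adjusted p = 0.0345). Higher were BATF3, an AP-1 family factor, at 1.00 (adjusted p = 0.0136), the scavenger receptor CD36 at 1.00 (adjusted p = 0.0462), RASGRP1, a Ras activator, at 1.14 (adjusted p = 0.0244), SGPP2 at 0.74 (adjusted p = 0.0358) and MAP3K8, a kinase bound by NF-kB p105, at 0.74 (adjusted p = 0.0422). The genes from RNU4-1 on had the same sign in 6 of 6 pairs, except MAP3K8 with 5 of the 5 measured.

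In carrier-treated cells 1 of 33 lists passed camera for 24 h against 6 h. MYC targets and ribosome biogenesis had a median of -0.38, with 19 of 22 members negative and 0 past limma's threshold over all genes, 3 at an unadjusted p under 0.05 (camera, adjusted p = 0.00187; adjusted p = 0.489 with an estimated correlation). With an estimated correlation 0 lists passed, and time cannot be told apart from chip position here.

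Chance assignment of labels within the pairs was examined with the 32 splits that part every pair. The real split was the 1 split with as many genes, 103, against a highest count of 0 in the others, and the 1 split with as many lists, 14, against a highest of 11. A share of 1 in 32 is the smallest these splits can give, so chance assignment is argued against for both counts but not excluded. The splits take both arrays of a pair as exchangeable, although the array labelled MLN120B lies first in 6 of 6 pairs. They address single arrays, and replicates may be only technical. The splits with up to 11 lists share most pairs with the real one, since turning a single pair leaves 5 as they are.

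KLHL24 and CCNG2, known FOXO targets, were lower in the arrays labelled MLN120B, which raised the hypothesis that FOXO targets were lower as a group. A list of 23 other FOXO targets, 9 of which are also in the fixed lists, had a median of -0.22, negative in 6 of 6 pairs (camera p = 0.00821; p = 0.0755 with an estimated correlation), and without those 9 members a median of -0.32 (camera p = 7.05e-04; p = 0.0383 with an estimated correlation, or 0.0765 when adjusted over the added lists). Of the 23 genes limma called 0 over all genes tested, and 2 were lower adjusted over the list alone, TSC22D3 at -0.64 and YPEL5 at -0.46. DEPP1, another known FOXO target, rose by 1.29, against the direction of the list. DEPP1 is not on the list, which was drawn up after the results had been seen. Within the list ZFP36L2 had a positive difference of 0.56 that did not pass. The values are consistent with a small group shift, whose direction rests on the labels, as does that of every difference here.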
